A study of Danio rerio with 34 samples.

How the data were processed

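RNA was measured in 18 testis libraries of adult zebrafish, 6 from fish given the carrier DMSO, 6 from fish exposed to 3 nM PCB126 and 6 from fish exposed to 10 nM. Exposure lasted 24 h and was followed by 7 days in clean water, per the labels' protocols. DNA methylation was measured by reduced representation bisulfite sequencing, which reads CpG-rich fragments cut with MspI, in 5 DMSO, 6 3 nM and 5 10 nM samples. The series describes its replicates as biological.

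For RNA, the deposited values are whole-number counts per gene, made by the authors and not normalized. The submitters' processing notes name FastQC, STAR, HTSeq and edgeR and the build GRCz10, without versions. The kit was stranded and the reads were 50 bases from one end, per the labels' protocols. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands, and close paralogs, are uncertain. All 18 tables hold 35117 gene identifiers, and 0 rows name no gene. Library totals ran from 16.2 to 29.8 M counts (M, 1e6), with a median of 26.6 M. At those totals a count of 3 equals 0.185 CPM in the shallowest library and 0.101 CPM in the deepest, which covers counting error only. No pair of libraries was identical, and the lowest chi-square per degree of freedom between replicates was 19.9, so all were kept as separate samples.

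For methylation, per-sample values were not analysed here. The authors' deposited tables list regions with a q-value, a mean methylation difference, a CpG number and 2 group means, as fractions that were turned into percent. The tables were kept by the authors at q under 0.05, per the file headers and names, which also name the program metilene. How its q-value treats CpGs and fish is not given in the sources used here. It is therefore not read as a measure of spread between fish. The headers do not name the 2 groups. The second mean was equal in both tables at 5 of 6 regions with identical coordinates, which is how it was read as the DMSO mean. Of these 5 regions, 4 had the same length, CpG number and nearly the same means as each other, so the reading rests on few separate cases. The names of the tables write the lower concentration as 0.3, whereas the labels give 3 nM, and the label is followed here. Coverage, aligner and the libraries behind each table are not given in the sources used here, so depth is unknown and no interval was computed. Coordinates are printed as the tables give them, on GRCz10 by the labels.

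Symbols came from a name table that covered 27000 of the identifiers. It gives some zebrafish genes the symbol of their human counterpart in capitals (CYP1A1 is zebrafish cyp1a), and some symbols belong to more than 1 identifier. No annotation of GRCz10 was used, so regions were not assigned to genes, and the planned test of expression at genes near regions, within 5 kb upstream, was not analysed here.

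Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, dispersions were estimated with the robust option, and a quasi-likelihood F-test was run in 1 fit of all 18 libraries with 15 residual degrees of freedom. That left 24053 genes. All tests were two-sided, and adjusted p-values are Benjamini-Hochberg values, called under 0.05. Standard errors (SE) of log2 fold changes were taken as the change divided by the square root of its F. CPM values, counts per 1e6 counts, use the TMM-scaled totals of the deposited counts. The test was checked on simulated counts for the 10 nM against DMSO comparison, run on 23478 genes. It called 14% of genes raised 1.5-fold, 50% raised 2-fold, 80% raised 4-fold and 26% lowered 2-fold, and 2 of 23281 unchanged genes. Each gene was drawn independently, so no simulated library could differ from its group in many genes at once. Real libraries did so, and these rates need not hold for them.

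The 29 gene lists hold 720 names, of which 681 matched an identifier, and include markers of cell types a testis sample could hold. Lists with at least 3 tested members were tested with fry in limma 3.58.1, whose directional p-value asks whether the members move, on balance, one way. It does not compare the list with other genes. Adjustment was over the lists of 1 comparison. Camera, which does compare a list with other genes, was run with a preset correlation of 0.01 and with an estimated one. Values given below with an estimated correlation are camera values and answer that other question. A list score per library is the mean over members of log2 CPM (prior count 2) minus the DMSO mean.

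Named genes were the AHR-responsive genes cyp1a, cyp1b1, cyp1c1, cyp1c2, ahrra and ahrrb. To these were added the 10 largest increases and 10 largest decreases among called genes with a symbol and a mean of at least 1 CPM (5 each way for 10 nM against 3 nM), and up to 4 members per list by smallest p. Lists, tests, named-gene rule and alternatives were fixed before the data were examined. For 10 nM against 3 nM that rule takes only the largest changes. ahr2 and CYB5A in comparisons where that rule does not take them, and tiparp, cyp1c2, CYP1B1 and CYP1A1 against 3 nM, were named after their values were seen.

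Alternatives were DESeq2 size factors, DESeq2 1.42.0 (Wald tests, with a likelihood ratio test for any difference), limma-voom with sample weights, no count filter, a filter of 1 CPM in 6 libraries, fits of the 2 compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, an FDR of 0.1 and leaving out each library. For regions they were q under 0.01, a difference of at least 20 percentage points and at least 10 CpGs. Fits without libraries that lie apart on the first principal component, and counts of regions with equal values (same length and CpG number, group means within 1 percentage point) taken once, were added after seeing the data. Both concentrations share the DMSO libraries, so 100 draws of unchanged groups at the DMSO means were put through the same fit, and the 6 DMSO libraries were split 3 and 3 in 20 ways. A correlation was taken as moved when it changed by more than the SD over those 20 splits, a yardstick chosen after the files were seen.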

Results

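PCB126 is a dioxin-like polychlorinated biphenyl that activates the aryl hydrocarbon receptor (AHR). The series asks how a short exposure changes gene expression and DNA methylation in the adult zebrafish testis. RNA was counted in 6 libraries per group, with totals of 16.2 to 29.8 M counts (M, 1e6) in DMSO, 21.8 to 29.1 M at 3 nM and 18.6 to 26.8 M at 10 nM. On the first principal component, which held 39.7% of the variance, 5 exposed libraries lay apart from the other 13. They were 3 nM replicates 4 (74.1) and 6 (77.2) and 10 nM replicates 1 (128.9), 5 (138.1) and 6 (48.4), and all others lay between -58.4 and -3.8. The share of counts from mitochondrial genes was 2.31% ± 0.47 in DMSO, 3.2% ± 1.02 at 3 nM and 4.73% ± 2.17 at 10 nM (SD, n = 6 each). The 5 libraries apart had the highest shares, 3.8% and 4.78% in the pair at 3 nM and 6.89%, 7.21% and 5.87% at 10 nM, in the order above, against at most 3.55% in the others.

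At 10 nM, genes that answer to AHR rose far above DMSO. CYP1A1 (ENSDARG00000098315), a monooxygenase of xenobiotic metabolism, went from 3.49 ± 1.08 CPM to 1798 ± 790 CPM (SD, n = 6), a log2 fold change of 9.0 ± 0.42 (SE, adjusted p = 3.28e-10). CYP1B1 rose by 6.35 ± 0.40 on the log2 scale, ahrra, which encodes a repressor of AHR, by 6.34 ± 0.56, and cyp1c1 by 4.25 ± 0.43. cyp1c2 rose less, by 1.83 ± 0.30 (adjusted p = 0.00297), and ahrrb, the other repressor gene, had a value of -0.13 ± 0.22 (adjusted p = 0.682). The receptor gene ahr2 rose by 1.80 ± 0.19 (adjusted p = 3.25e-05), tiparp, a target that limits AHR activity, by 1.44 ± 0.12, and CYB5A by 4.32 ± 0.35. Of 15 tested AHR target genes 10 rose and 0 fell, also when adjusted over the list alone, and the list was called (fry adjusted p = 4.37e-08; adjusted p = 0.000154 with an estimated correlation). Its median log2 fold change was 1.84, and 1.27 without the 5 libraries apart.

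**Figure D1:**
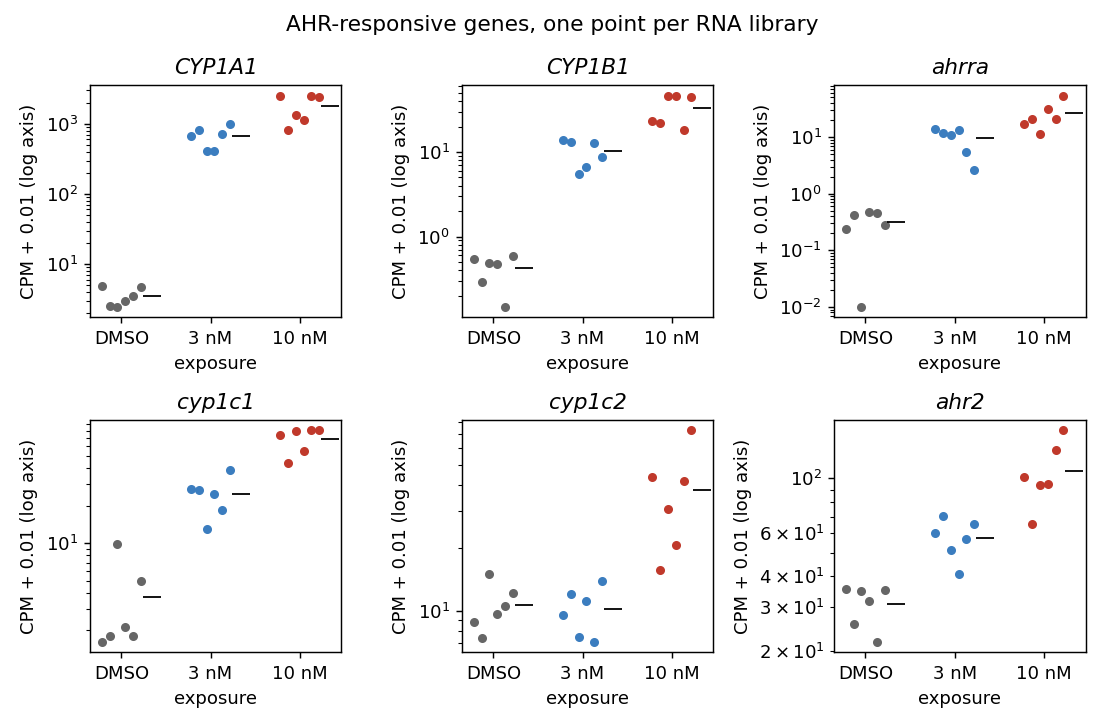
Counts per 1e6 counts (CPM, plus 0.01, on a log axis) of 6 AHR-responsive genes in DMSO, 3 nM and 10 nM libraries, 1 point per library with a bar at the group mean. CYP1A1 means were 3.49, 674 and 1798 CPM, while cyp1c2 means were 10.6, 10.2 and 37.7 CPM.

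Meiosis genes fell at 10 nM. MSH4, needed for meiotic crossovers, fell by 0.93 on the log2 scale (SE 0.16, adjusted p = 0.00336), and the meiotic cohesin genes rec8b and rad21l1 fell by 0.83 (SE 0.14) and 0.54 (SE 0.10). Of 25 tested members 12 fell and 0 rose, 18 falling when adjusted over the list alone (fry adjusted p = 0.000324). Camera gave an adjusted p of 0.111 with an estimated correlation and 1.43e-09 with the preset one. List scores in the 10 nM libraries ran from -0.60 to -0.39 and those in DMSO from -0.17 to 0.31. Cell cycle genes were called lower too (adjusted p = 0.00255), with 4 of 25 falling, among them kif11 (-0.57) and bub1 (-0.92), and 6 falling and 1 rising when adjusted over the list alone (adjusted p = 0.225 with an estimated correlation). Without the 5 libraries apart the meiosis list had an adjusted p of 0.0108 and the cell cycle list one of 0.0683, while their median log2 fold changes went from -0.51 to -0.53 and from -0.24 to -0.27.

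Immediate early genes and interferon response genes rose at 10 nM. JUNB (ENSDARG00000104773) rose by 1.72 ± 0.23 and egr1, a transcription factor induced by growth signals, by 1.57 ± 0.27, and 10 of 21 members of that list rose, 13 when adjusted over the list alone (fry adjusted p = 0.00255; adjusted p = 0.225 with an estimated correlation). Among interferon response genes irf1b rose by 0.71 ± 0.15 and isg15 by 1.17 ± 0.29, with 12 of 25 rising, 19 when adjusted over the list alone (fry adjusted p = 0.000579; adjusted p = 0.138 with an estimated correlation). Without the 5 libraries apart these lists had adjusted p-values of 0.000955 and 0.0150, and their median log2 fold changes went from 0.68 to 0.26 and from 0.63 to 0.44. Retinoid genes were called higher (adjusted p = 0.00785), with raraa at 0.82 ± 0.16 and rbp5 at 1.67 ± 0.38 rising and STRA6 falling by 0.72 (SE 0.16). In all 6 rose and 1 fell of 30, or 8 and 1 when adjusted over the list alone (adjusted p = 0.409 with an estimated correlation; adjusted p = 0.3 without the 5 libraries, where the list's median log2 fold change was 0.13 and not 0.36).

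Leukocyte, intestine and mitochondrial genes rose at 10 nM on average, with wide differences between libraries. The neutrophil lysozyme gene lyz was 4.56 ± 1.40 CPM in DMSO and 250 ± 332 CPM at 10 nM (SD, n = 6), a change of 5.78 ± 0.90 (SE, adjusted p = 0.00184), which was 2.23 ± 0.30 without the 5 libraries apart. For mmp13a the change was 6.15 ± 1.05, and 1.82 ± 0.27 without those libraries. Of 41 leukocyte genes 12 rose, 18 when adjusted over the list alone (fry adjusted p = 0.0240; adjusted p = 0.409 with an estimated correlation), and the leukocyte scores of 10 nM replicates 1, 5 and 6 were 1.82, 1.82 and 1.27 against at most 0.44 in DMSO. Of 17 intestine genes 4 rose, the cadherin gene CDH17 by 3.55 ± 1.0, and 4 when adjusted over the list alone (fry adjusted p = 0.0240; adjusted p = 0.412 with an estimated correlation). CDH17 had 1983 and 1890 counts in 10 nM replicates 1 and 5, 56 to 115 in the other 10 nM libraries and 42 to 143 in DMSO. Of 13 mitochondrial genes 11 rose, 13 when adjusted over the list alone (fry adjusted p = 0.0240; adjusted p = 0.409 with an estimated correlation). Without the 5 libraries these lists had adjusted p-values of 0.3, 0.469 and 0.391, and their median log2 fold changes went from 0.96 to 0.12, from 0.82 to 0.11 and from 1.26 to 0.28. The sizes of the increases of jac2 (8.96 ± 1.77), jac7 (6.48 ± 1.43) and fxyd12 (6.36 ± 1.99) rested on few libraries. jac2 reached 326 CPM in 10 nM replicate 6 and at most 12 CPM in the others, and fxyd12 had a value of -0.51 without the 5 libraries. A rise of jac2 did not rest on replicate 6 alone. Its counts were 1 to 6 in DMSO, 19 to 256 at 3 nM and 4 to 185 in the other 10 nM libraries.

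**Figure D2:**
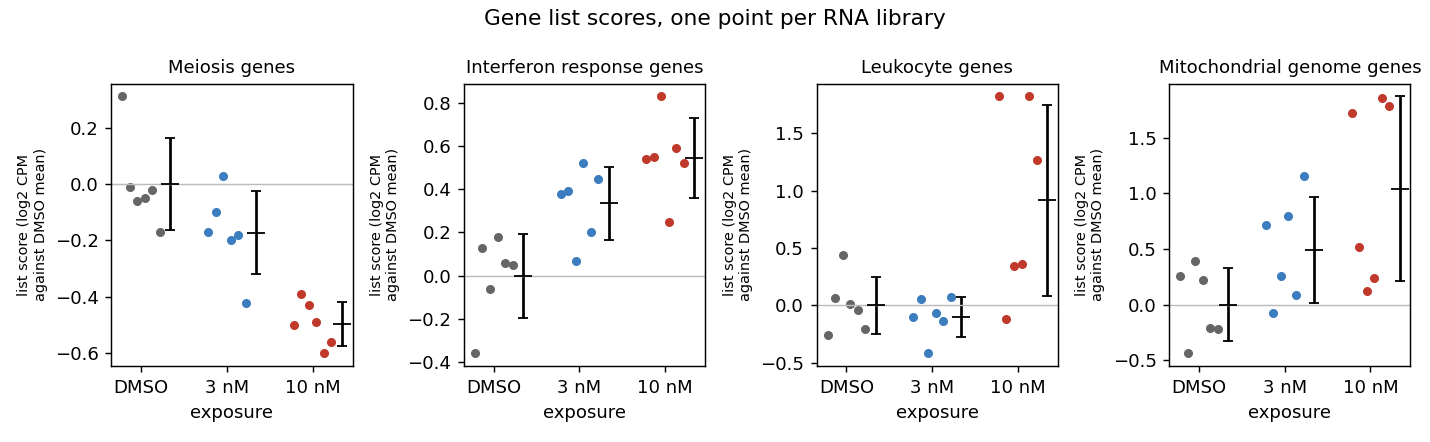
Scores of 4 gene lists (mean log2 CPM against the DMSO mean), 1 point per library, with the group mean and SD. The meiosis scores of the 10 nM libraries lie between -0.60 and -0.39, whereas their leukocyte scores spread from -0.12 to 1.82.

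Among the largest decreases at 10 nM, FST (ENSDARG00000057992), which encodes the activin antagonist follistatin, fell from 58.6 ± 22.9 to 9.40 ± 2.08 CPM (SD, n = 6), a log2 fold change of -2.64 ± 0.27 (SE, adjusted p = 1.73e-05), and ITGBL1 fell by 1.72 (SE 0.15). Steroidogenic enzyme genes CYP17A1 (-1.39 ± 0.31), cyp17a2 (-1.20 ± 0.30) and CYP11A1 (ENSDARG00000092696, -0.87 ± 0.24) fell, although of the 24 genes of their list 1 rose and 3 fell and the list was not called (adjusted p = 0.266). Without the 5 libraries apart CYP17A1 had a log2 fold change of -0.96 ± 0.38 (SE, adjusted p = 0.192).

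In all, 2609 of 24053 genes differed between 10 nM and DMSO at an adjusted p under 0.05, 1781 higher and 828 lower, and 9 of 29 lists were called. In fits chosen after seeing the data, the count was 468 without the 5 libraries apart (251 higher, 217 lower). It was 100 without the 3 of 10 nM alone (87 higher, 13 lower). Of the 468, 388 were among the 2609. Of the 2609, 2581 of 2604 tested kept their sign without the 5, at a median fold change ratio of 0.63 on the log2 scale. The count of 2609 also fell by over 1.5 times without DMSO replicate 1 (1131), 2 (826), 4 (1328), 5 (1481) or 6 (1286) or 10 nM replicate 1 (965), 5 (894) or 6 (1457).

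At 3 nM the same AHR-responsive genes led the changes. CYP1A1 reached 674 ± 233 CPM (SD, n = 6), a log2 fold change of 7.59 ± 0.40 (SE, adjusted p = 2.51e-09), ahrra rose by 4.91 ± 0.53, CYP1B1 by 4.62 ± 0.38, cyp1c1 by 2.78 ± 0.41 and CYB5A by 2.63 ± 0.33. cyp1c2 had a value of -0.06 ± 0.30 (adjusted p = 0.936) and ahr2 one of 0.90 ± 0.19 (adjusted p = 0.0560). Of 15 AHR target genes 5 rose, 6 when adjusted over the list alone (fry adjusted p = 9.09e-06; adjusted p = 0.000509 with an estimated correlation). The muscle kinase gene musk rose by 2.58 ± 0.35 and timd4, a phosphatidylserine receptor gene, by 3.92 ± 0.53.

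Adipocyte genes fell at 3 nM. fabp4a, a fatty acid binding protein of adipocytes, went from 174 ± 64.6 to 52.6 ± 16.6 CPM (SD, n = 6), a log2 fold change of -1.73 ± 0.25 (SE, adjusted p = 0.00239), and LPL (ENSDARG00000087697), lipoprotein lipase, fell by 1.31 (SE 0.26). Of 15 adipocyte genes 2 fell and 0 rose, 4 falling when adjusted over the list alone (fry adjusted p = 0.00488; adjusted p = 0.0312 with an estimated correlation), with an adjusted p of 0.109 and a median log2 fold change of -0.44, from -0.67, without the 5 libraries apart. Outside that list, FST fell by 2.15 (SE 0.26), ITGBL1 by 1.36 (SE 0.15), the fibronectin gene FN1 (ENSDARG00000006526) by 1.55 (SE 0.29) and the activin subunit gene INHBA (ENSDARG00000012671) by 1.45 (SE 0.26). The smooth muscle and connective tissue list was not called (1 of 29 genes fell, adjusted p = 0.0731). In all 50 genes differed, 31 higher and 19 lower, and 2 lists were called, or 4 without 3 nM replicate 2. The count of genes was 65 without the 5 libraries, 37 of them among the 50, and it fell by over 1.5 times without DMSO replicate 1 (25), 3 (27), 4 (33) or 6 (29) or 3 nM replicate 4 (27), 5 (25) or 6 (29).

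Genes called at 3 nM mostly also changed at 10 nM. Of the 50, 29 were higher and 16 lower at both concentrations and 0 went opposite ways. Simulated unchanged groups that share the DMSO libraries had a mean overlap of 0.01 and at most 1, but with at most 1 gene called at 10 nM and 2 at 3 nM these draws say little about an overlap of longer lists. The overlap of 45 was over 1.5 times lower without DMSO replicate 1 (22), 3 (26) or 6 (26) or 3 nM replicate 4 (26), 5 (23) or 6 (29). Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.684 against a simulated 0.498, and a covariance of 0.262 against 0.067. The draws varied each gene independently and held no libraries apart, whereas both exposed groups did. The excess over the simulated values therefore does not show a shared response to exposure. With separate sets of 3 DMSO libraries the correlation averaged 0.482 (0.306 to 0.587 over 20 splits) and the covariance 0.216. The simulated values are for shared DMSO libraries, so they are no yardstick for separate sets, which also hold fewer libraries each.

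Set directly against 3 nM, 10 nM raised AHR target genes further. cyp1c2 was higher by 1.89 ± 0.31 on the log2 scale (adjusted p = 0.0288), CYP1B1 by 1.73 ± 0.31 (adjusted p = 0.0392) and tiparp by 0.75 ± 0.12 (adjusted p = 0.0288), while CYP1A1 had a value of 1.42 ± 0.30 (adjusted p = 0.0519). The list was called with 4 of 15 genes rising, 8 when adjusted over the list alone (fry adjusted p = 0.000228; adjusted p = 0.00168 with an estimated correlation). The retinoid (0.00380), leukocyte (0.0147), adipocyte (0.0109) and blood vessel (0.0109) lists were higher and the meiosis (0.00798) and cell cycle (0.00798) lists lower by adjusted p. With an estimated correlation the blood vessel list had an adjusted p of 0.0755 and the other 5 lists one of 0.0402. Over all genes 1 retinoid gene and 3 leukocyte genes passed in edgeR, and 0 genes of the other 4 lists did. Adjusted over each list alone 10, 25, 5, 8, 8 and 0 genes passed, in that order. Without the 5 libraries apart 1 list, the AHR target genes, was called, with a median log2 fold change of 0.73 where it was 1.42 with all libraries, while the medians of the other 6 lists went from 0.22 to 0.20, 1.12 to 0.32, 0.36 to 0.29, 0.56 to 0.23, -0.33 to -0.36 and -0.25 to -0.24, in that order. In all 31 genes differed, 29 higher and 2 lower, a count that was 0 in edgeR without the 5 libraries (1663 genes at an unadjusted p under 0.05) and that moved by over 1.5 times, to between 0 and 355, in each of the 18 fits that left out a library. Any difference among the groups was called for 1091 genes, a number over 1.5 times lower without DMSO replicate 1 (618), 2 (477), 4 (588), 5 (633) or 6 (569) or 10 nM replicate 1 (480), 5 (486) or 6 (569).

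Methylation in the authors' deposited tables was more often lower than higher after exposure. At 3 nM the authors' deposited table lists 37 regions, 10 higher and 27 lower than DMSO, and at 10 nM it lists 92, 12 higher and 80 lower, each with at least 10 CpGs. In the authors' deposited table for 10 nM, the largest increase was on chromosome 1 from 50456343 to 50456668, with 66.0% methylation against 12.3% in DMSO (q = 4.9e-08). The largest decrease in the same authors' deposited table was on chromosome 4 from 50966939 to 50967355, with 36.3% against 89.6% (q = 1.3e-23). These q-values are the authors' own, and how far fish of a group differed cannot be seen from group means. At 3 nM the authors' deposited table gives the largest increase on chromosome 9 from 53005255 to 53005469 (46.9% against 24.4%) and the largest decrease on chromosome 19 from 19543571 to 19544027 (54.5% against 88.7%). Chromosome 4 held 9 of the 37 and 34 of the 92 regions in the authors' deposited tables. The share of covered CpGs on that chromosome is not known here, so no enrichment can be read from these counts. Many of the 34 lay close together, as between 76317209 and 76331621, where some had equal values in the authors' deposited table.

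Regions shared by both concentrations changed in the same direction. There were 19 overlaps of at least 1 base in the authors' deposited tables, 5 higher and 14 lower, joining 18 regions at 3 nM and 17 at 10 nM, and the authors' deposited table of overlaps holds the same 19. They are not all separate, since 6 of the 19, 4 higher and 2 lower, have equal values (group means within 1 percentage point) in another of them in the authors' deposited tables. With equal regions, and overlaps of the same region, at 3 nM counted once, 14 are left, a choice made after seeing the data. That rule can miss copies of another length or CpG number, so 14 may be too many. In the authors' deposited table for 10 nM, a set of 7 equal regions (144 bases, 11 CpGs) lay near several lower overlaps. An example is chromosome 20 at 10381067, beside the region from 10379108 to 10380070. The absolute difference was larger at 10 nM in all 19 by the authors' deposited tables. Only 6 of the 19 had identical coordinates, so the others set unlike stretches side by side. On chromosome 4 from 33606868, the difference was -13.7 percentage points at 3 nM (to 33608576, 123 CpGs). At 10 nM it was -38.3 (to 33608772, 88 CpGs) in the authors' deposited tables. Both comparisons share their DMSO group, so part of this overlap may come from it, and no test was possible on group means. Of the 37 regions 14, and of the 92 regions 43, had in the authors' deposited tables the same length and CpG number as another region and group means within 1 percentage point of it.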

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

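The tests of leukocyte, Sertoli and exposure effects on the libraries apart, of cyp1c1 reads, and of other splits were chosen after the results were seen, as were the fits without those libraries, whereas the thinning of depth and the gene tests of 10 nM against 3 nM were chosen before. Of 132 groups of 6 values examined, 16 held a library far from the others. The 6.60 that chance would give holds for independent, normally distributed values. Most groups were CPM of genes picked for large changes in the same libraries, so 6.60 is no yardstick and the excess shows nothing. In DMSO, replicate 3 had 16.2 M counts, replicate 1 had high CPM of fxyd12 (1.47), prok2 (24.4), OAT (47.0) and SLC10A4 (30.5), replicate 2 of nkl.2 (5.79) and replicate 3 of thrsp (13.6). At 3 nM, replicate 5 had high CPM of jac2 (10.9), replicate 1 of fxyd12 (27.7) and thrsp (2.72), replicate 2 of LPL (23.7) and replicate 6 of INHBA (5.15). At 10 nM, replicate 6 had high CPM of jac2 (326) and jac7 (281), replicate 5 of fxyd12 (184) and replicate 1 of mmp13a (352).

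The test of 10 nM against 3 nM passed for mmp13a (log2 fold change 5.46), lyz (4.57), HTRA3 (3.16), CRABP2 (2.73), EMILIN2 (2.40), txlnbb (-1.26) and SERINC3 (-0.53). For the 31 genes of that comparison chance in how the libraries are grouped was not excluded, since 6 of 100 splits called as many and the highest other split called 3111. Why another split called so many was not tested. For its 7 lists 2 of 100 splits gave as many (highest other 8). For 10 nM against DMSO 1 of 100 splits, the real one, reached 2609 genes (highest other 1700) and 9 lists (highest other 8). For 3 nM the real split alone, 1 of 100, reached 50 genes (highest other 5) and 2 lists (highest other 1), and for any difference it alone, 1 of 100, reached 1091 (highest other 970).

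The 5 exposed libraries lie apart on the first component, and without them 468 genes were called at 10 nM, with 2581 of 2604 calls keeping their sign at a median log2 ratio of 0.63, but why the count fell was not tested (it was 826 without DMSO replicate 2). Depth is argued against as what sets them apart, because with every library thinned to 16.2 M counts 5 of the 5 stayed apart and 2250 genes were called at 10 nM. More leukocyte RNA may be a source for the 3 libraries of 10 nM, whose lowest leukocyte score was 1.27 against at most 0.44 in DMSO, but not for the 2 of 3 nM, whose higher score was 0.07. Why all 5 had the highest mitochondrial shares (at least 3.8% against at most 3.55% in the others) was not tested. The 5 also had the lowest TMM factors (at most 0.927 against at least 0.965). Their 10 most counted genes held the highest shares of counts (at least 6.36% against at most 5.2%). Sample or RNA quality was not examined and stays open. A lower share of germ cells with other cell types raised alike is argued against in the 3 of 10 nM. Their leukocyte minus Sertoli scores were at least 1.54 (DMSO at most 0.23). The mean difference over all 6 libraries was 1.17 (exact permutation p = 0.0714). In the 2 of 3 nM, Sertoli scores of at most -0.32 were narrowly below the limit (DMSO mean minus 2 SD, -0.27), and 3 nM replicate 1, not apart, had -0.25. Leukocyte minus Sertoli in 3 nM replicate 6, 0.39, was within 2 SD of DMSO (0.48), so these 2 libraries do not decide it. Scores are RNA levels, and whether Sertoli genes kept their expression per cell was not tested. An effect of exposure itself stays open too, with 5 of 12 exposed and 0 of 6 DMSO libraries apart (Fisher's exact test p = 0.114, two-sided), since with 5 libraries apart no split towards exposure gives a lower p and the test could not pass 0.05 that way.

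Regions at different places in the authors' deposited tables share length and CpG number and have group means within 1 percentage point of each other, as for 7 regions of 58 bases on 7 chromosomes or scaffolds with 10 CpGs. All 77 pairs of equal length and CpG number at 10 nM had DMSO means within 1 percentage point, which restates the pattern. Some were equal in every printed digit in the authors' deposited table, as on chromosomes 14 (30817319), 18 (12547869) and 19 (20893850). Each had 30.14% against 53.0% (q = 0.00082), so such regions may not be separate measurements. Sequence was not examined, so reads shared between repeat copies were not tested, and no biological explanation was tested.

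cyp1c2 was higher at 10 nM and not at 3 nM, whereas its paralog cyp1c1 was higher at both. Reads of cyp1c1 counted for cyp1c2 would need 41.6% of the cyp1c1 increase and would then give a log2 fold change of 0.87 at 3 nM, against -0.06 ± 0.30 (SE) measured, so this was argued against. A steeper response of cyp1c2 to concentration may remain as a hypothesis, untested by other concentrations.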

How the results depend on the processing

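The fits without libraries apart and the counts of equal regions taken once were chosen after seeing the data. Where a value moved, the cause was not tested. Main counts were 2609 genes at 10 nM, 50 at 3 nM, 31 for 10 nM against 3 nM and 1091 for any difference, in that order below. They were 1077, 100, 89 and 700 with 1 surrogate variable, 4626, 311, 701 and 3213 with DESeq2, and 5502, 79, 303 and 2843 at an FDR of 0.1. Without the 5 libraries apart 468 genes were called at 10 nM, 0 for 10 nM against 3 nM and 171 for any difference, and without the 3 of 10 nM the counts were 100, 118, 0 and 88. Fits of the 2 groups alone gave 1699 at 10 nM and 0 for 10 nM against 3 nM. limma-voom gave 150 at 3 nM and 14 for 10 nM against 3 nM, and the filter of 1 CPM gave 64 for the latter. Leaving out 1 library gave 826 to 3855, 25 to 55, 0 to 355 and 477 to 1609 genes.

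With the replicate block the counts were 684, 26, 0 and 184, and the overlap 23. No pairing by number was found, as same-numbered libraries had correlations of -0.486 to 0.338 and 1 library correlated best with its own number in both other groups. A weaker pairing could be missed by this check and was not excluded.

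The overlap of 45 genes became 69 with 1 surrogate variable, 220 with DESeq2, 70 at an FDR of 0.1 and 115 with limma-voom, and 22 to 48 with 1 library left out. The correlation of 0.684 became 0.565 with 1 surrogate variable, 0.572 with no filter, 0.482 with separate sets of 3 DMSO libraries, 0.529 without the 3 libraries of 10 nM, and 0.605 to 0.709 with 1 library left out.

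Lists called were 9 at 10 nM, 2 at 3 nM and 7 for 10 nM against 3 nM. Camera with a preset correlation gave 11 at 3 nM and 17 for 10 nM against 3 nM, and with an estimated one 1 at 10 nM. At 10 nM camera with the preset correlation gave adjusted p-values of 1.43e-09 for meiosis, 0.000121 for cell cycle, 3.06e-06 for immediate early and 4.91e-06 for interferon genes. Those for leukocyte, mitochondrial, intestine and retinoid genes were 6.4e-07, 1.93e-07, 0.0309 and 0.0559. With 1 surrogate variable 5 and 4 lists were called at 10 and 3 nM, without the 5 libraries apart 4, 1 and 1, and without the 3 of 10 nM 4, 4 and 1. Leaving out 1 library gave 6 to 10, 2 to 4 and 7 to 9.

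Among named genes, fxyd12 at 10 nM changed sign with 1 surrogate variable (-0.28), without the 5 libraries (-0.51) and without the 3 (-0.49), and VIL1 without the 5 (-0.056) and without the 3 (-0.036). Other called results of named genes kept their sign but lost their call, 72 without the 5 libraries (50 kept it) and 88 without the 3 (35 kept it). With the replicate block 61 lost it and 64 kept it, with 1 surrogate variable 49 and 75, with limma-voom 40 and 85, and with DESeq2 0 and 121. Regions at 3 nM numbered 24 with a difference of at least 20 percentage points, and those at 10 nM 61 with equal regions taken once. The rule for equal regions can miss copies of another length or CpG number. The minimum of 10 CpGs removed no region and says nothing on stability. The expression of genes near regions, with its wider window, was not run.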

Other observations

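The values in this part were picked after the scores were seen. Other tissues differed widely between libraries, in lists that were not called. Exocrine pancreas genes had scores from -2.46 to 3.34, with DMSO replicate 4 at 3.34 and 10 nM replicates 4 and 5 at 2.6 and 2.47. Oocyte genes had a score of 3.59 in 3 nM replicate 4 and 1.90 in 10 nM replicate 5 against at most 0.22 in DMSO, and 0 of 24 were called at 3 nM (fry adjusted p = 0.215), or 14 when adjusted over the list alone. Skeletal muscle genes had scores of 1.35 and 1.06 in DMSO replicates 1 and 4.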
